A study of Mus musculus with 4 samples.

How the data were processed

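Total RNA of mouse CGR8 embryonic stem cell-derived cardiomyocytes was measured on 4 Agilent 1-colour (Cy3) gene expression arrays, 2 of cells transfected with a scrambled RNA (siScr) and 2 of cells transfected with an RNA against Erbb4 (siErbB4). Per the labels' protocols, transfection lasted 48 hours, the medium held 2% serum, and the dye-labelled copy RNA was made from 200 ng of RNA. The arrays were extracted with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. Per the file headers, the processed intensity of each spot had its background subtracted and was detrended within the array, and it was not scaled between arrays. The raw median intensity of each spot and of its local background was deposited beside it. Other columns used are the flags that Feature Extraction set, per the file headers, for spots well above background, saturated or outlying. The authors' deposited value table is on the log2 scale, and its scale and centring were found by setting it against the scanner values. Each column equalled the log2 processed signal minus the array's 75th percentile, with a correlation of 1 across probes and a largest difference of 0.00328. The column medians were -3.81, -3.83, -3.84 and -3.86 for siScr 1, siScr 2, siErbB4 1 and siErbB4 2, so the table was not centred per probe, and none of scale, centring or direction stayed unknown.

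Of 44397 spots, 1377 control spots were left out, and 43020 spots of 39429 probes remained. Outlier-flagged spots were left out (131 to 179 per array), which removed 12 probes, and 0 spots were saturated. Spots of a probe were averaged. The log2 processed signal minus the array's 75th percentile over non-control probes was analysed. Probes were kept when well above background on both arrays of at least 1 group, which left 25690. The scanner files give an accession per probe, and 27508 probes were named through an unversioned RefSeq accession in a table of assembly GRCm38.p6. The other 11921 probes have no symbol here and stayed in the tests under their own identifiers. The array's annotation names another genome build, so no coordinates are given. Of several probes of a gene the one with the highest mean was used. This affected 3977 genes, of which 3 had kept probes 0.58 or more from 0 in opposite directions. The test covered 20726 features, 14993 named genes and 5733 unnamed.

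Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The model left 2 residual degrees of freedom and a prior of 2.06, and the median SE was 0.177. Intervals are 95% intervals of limma's estimate. A gene not well above background on either array of a group has only a bound there. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background (9.14 to 12.0) and the probe's own signal, as means of scaled log2 values. The Erbb4 probe, too dim for the filter, was fitted with all 32388 unfiltered features.

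The 28 gene lists came from textbook knowledge, and the lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of 656 distinct listed genes 590 were tested. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. The camera test compares a list with the other genes, and fry asks whether its genes move, on balance, one way. The rule names Erbb4 and the tested ERBB genes, and up to 12 called genes per direction. Where fewer were called it names the 8 genes with the lowest p, an absolute log2 difference of at least 0.58, a symbol and no overlap between the groups. It also names from each list the 2 genes with the lowest p where none was called. Genes named outside the rule are said to be so, and some genes that the rule names are not reported here.

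The fit was tested on simulated data, with 200 changed features in each of 20 simulations of the siErbB4 against siScr comparison over 20726 features. With the observed spread between arrays, 3.73% of 2-fold, 80.7% of 4-fold and 95% of 8-fold changes were called, none with a wrong sign, beside 9.75 false calls per simulation. A list of 25 genes shifted by 0.4 was called by camera in 20 of 20 simulations and with an estimated correlation in 0, and 0 of 540 unshifted lists were called. The simulated arrays varied independently, while in the data the deviations of arrays with the same replicate number from their group means correlated at 0.679. The simulated rates of calls and false calls therefore need not hold for the data. The simulated genes also varied independently of each other. In the data the estimated correlation was 0.485 within the pluripotency list and 0.987 within the cell cycle list. The simulated counts therefore do not give camera's rate of false calls on these lists.

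Alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter and a stricter filter on dim probes, the mean of a gene's probes, every probe separately, the replicate number as a block, the deposited value table, a variance trend, array weights, other thresholds, and each array left out in turn. Normexp used the median spot signal, because the mean spot signal that had been planned is not among the columns used here. All 4 arrays lie on 1 slide, so slide could not act as a batch. No pair of arrays held identical values.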

Results

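Gene expression was measured in cardiomyocytes grown from CGR8 cells, a mouse embryonic stem cell line, after transfection for 48 hours with a small interfering RNA against Erbb4 (siErbB4) or with a scrambled control RNA (siScr). Erbb4 encodes a receptor tyrosine kinase of the epidermal growth factor receptor family that binds neuregulins. Each group held 2 samples, and each of the 4 samples was hybridised to its own 1-colour Agilent array, all on 1 slide. The 75th percentile of the processed signal lay between 878 and 989 across the arrays, and 64.8% to 68.5% of probes were well above background. The number of arrays limits the precision of every value. Nothing in the sources used here says that the replicates came from separate cultures, so the p-values measure only the spread between these samples. Values given below argue against scaling, hybridisation or scanning as the whole source of that spread. Between the replicate numbers 1085 features were called, 962 with quantile normalization, and spike-in probes differed by a median of 0.0762 against 1.14 for called genes. A technical source before hybridisation stays open. The sample titles and the transfection field set the groups. Other labels differ from them: the description of both siErbB4 samples names the scrambled RNA, and the source name of siErbB4 replicate 2 names ErbB5. The growth protocol gives an incubation of 6 or 24 hours without saying which samples had which.

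The target of the knockdown came first. Among the probes with a symbol here, Erbb4 was read by 1, whose processed signal was 9.02 and 11.9 in the siScr arrays and 2.83 and 15.0 in the siErbB4 arrays. It was well above background on 1 of the 4 arrays, siErbB4 replicate 2, so its difference is no measure of the knockdown, and the probe does not check which samples carried it. In a fit of these dim values, run without the filter, the Erbb4 log2 difference (siErbB4 minus siScr) was -0.68 with a standard error (SE) of 0.90 and a 95% interval of -3.22 to 1.86. Its limma p, adjusted by the Benjamini-Hochberg method, was 1.00. With normexp the difference was -0.03, and without siErbB4 replicate 1 it was 0.53. The directions below are therefore those of the samples labelled siErbB4 against those labelled siScr.

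Of the ERBB receptors and ligands, 8 of 15 listed genes were bright enough to test, and none passed the test. Erbb2, the usual dimerisation partner of Erbb4 in heart muscle, had a log2 difference of -0.07 (SE 0.22, 95% interval -0.67 to 0.53). The neuregulin gene Nrg1 gave -0.05 (SE 0.26) and Nrg2, well above background on 1 of the 2 siScr arrays, gave 0.53 (SE 0.65; -0.04 with normexp). Among the other ligands, Hbegf gave -0.13 (SE 0.23), Tgfa -0.16 (SE 0.16), Egf 0.01 (SE 0.16) and Epgn -0.15 (SE 0.35). Egfr gave 0.09 (SE 0.63) from the brightest of its 3 kept probes and -0.27 from their mean.

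Between the groups, genes of undifferentiated stem cells were higher as a list in the siErbB4 arrays, and genes of cholesterol synthesis were lower as a list. Both calls, made by camera with a preset correlation, were lost with an estimated correlation (adjusted p = 0.935 for each), and the cholesterol call also ended without siScr replicate 1. In simulations, camera with an estimated correlation called 0 of 20 lists shifted by 0.4, so a call lost with it does not show an unchanged list. The median log2 difference was 0.42 over 23 pluripotency genes and -0.26 over 25 cholesterol genes. Single genes with the lowest p included the chemokine gene Cxcl10, at 3.73-fold the siScr level, and the major urinary protein gene Mup18, at least 6.02-fold lower in processed signal (log2 difference -0.69 with normexp). No single gene passed the test across all genes. With limma and the Benjamini-Hochberg method, 0 of 20726 genes and unnamed features were called at an adjusted p under 0.05, and 366 had an unadjusted p under 0.05, of which 182 were higher and 184 lower, where chance gives 1036. The lowest adjusted p by limma was 0.569. The error of this fit holds a difference shared by same-numbered arrays of both groups. With the replicate number as a block, 1547 features had an unadjusted limma p under 0.05 and 0 were called. Groups did not overlap at 6001 features, or 29.0%, where chance gives 33.3%. A log2 difference of 1 or more in size was found at 121 features, 61 higher and 60 lower. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333.

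Genes with the lowest p in each direction are given as values, since none of them passed the threshold. Higher in the siErbB4 arrays were Cxcl10, an interferon-inducible chemokine (log2 difference 1.90, SE 0.33), and the lymphocyte protease gene Gzmm (1.46, SE 0.18). Lexm gave 1.08 (SE 0.17), the BCL2 family gene Bcl2l14 0.83 (SE 0.15) and the bestrophin gene Best2 0.74 (SE 0.14). Lexm was well above background on 1 of the 2 siScr arrays. Olfr47, an olfactory receptor gene, and Gab2, an adaptor of receptor tyrosine kinases, were not well above background on either siScr array and were at least 2.34-fold and at least 1.21-fold higher in the siErbB4 arrays.

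Lower in the siErbB4 arrays were Tm4sf1 (log2 difference -1.30, SE 0.22) and the ferritin receptor gene Scara5 (-0.76, SE 0.13), the latter well above background on 1 of the 2 siErbB4 arrays. The other genes on this side were not well above background on either siErbB4 array, so each has only a bound. Mup18 was at least 6.02-fold lower, the lipase-related gene Pnliprp2 at least 2.97-fold, the calpain subunit gene Capns2 at least 1.71-fold and Fam217a at least 1.61-fold. Sost, which encodes the Wnt antagonist sclerostin, was at least 1.39-fold lower and the Mediator gene Med12l at least 1.36-fold. With normexp background correction and an offset of 50, which shrinks the differences of dim probes, Mup18 was at -0.69, Pnliprp2 at -0.59, Sost at -0.28, Scara5 at -0.24, Capns2 at -0.21, Med12l at -0.11 and Fam217a at -0.10. Of the higher genes, Bcl2l14 was then at 0.26, Best2 at 0.16, Lexm at 0.14, Gab2 at 0.09 and Olfr47 at 0.02. Mup18 belongs to a family of near-identical genes, so its probe may read other members. Adjusted limma p-values by the Benjamini-Hochberg method were 0.569 for Mup18, 0.946 for Sost and 1.00 for the rest.

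**Figure D1:**
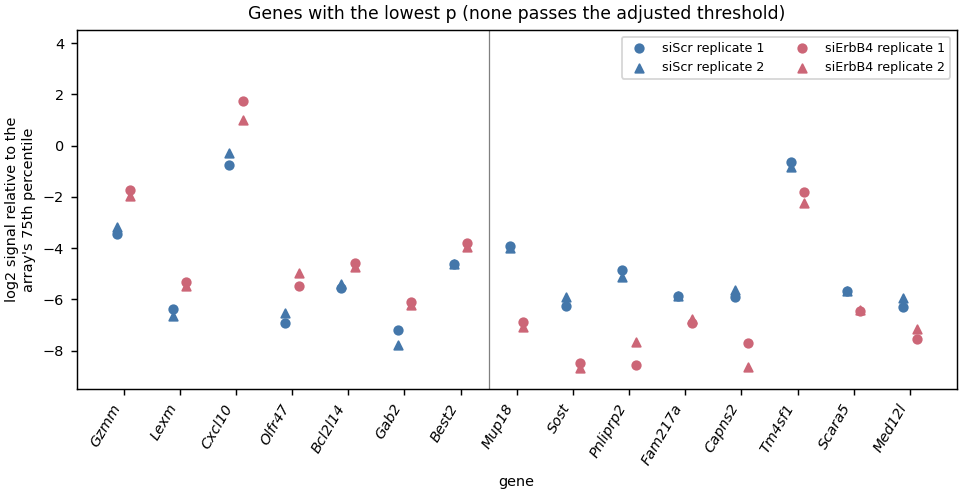
Log2 signal relative to each array's 75th percentile (vertical axis) for genes with the lowest p in each direction, with 1 point per array, siScr in blue and siErbB4 in red. The arrays of each group lie on opposite sides for every gene shown, because only genes without overlap between the groups were chosen. Mup18 has the lowest adjusted limma p, 0.569.

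The pluripotency list rose in the siErbB4 arrays. All 23 listed genes were tested, 21 had a positive log2 difference, and at 15 of them both siErbB4 arrays lay above both siScr arrays. The camera test with a preset correlation gave an adjusted p of 8.08e-10 (Benjamini-Hochberg over 28 lists), and the adjusted p = 0.935 with an estimated correlation. No member was called over all genes, and 0 were called when adjusted over the list alone. Tcl1, a cofactor of AKT kinases, had the lowest p, with a log2 difference of 0.61 (SE 0.15), followed by Fbxo15 at 0.56 (SE 0.18). Chosen after their values were seen, Pou5f1, a core transcription factor of the pluripotent state, gave 0.92 (SE 0.57; 0.19 to 1.65 with arrays left out), while Nanog at -0.13 (SE 0.17; 0.18 with the mean of its probes) and Klf5 at -0.19 (SE 0.29) were the members on the other side. Against the siScr mean, the list's median was 0.65 in siErbB4 replicate 1 and 0.19 in siErbB4 replicate 2. These are also the medians without siErbB4 replicate 2 and without siErbB4 replicate 1. As replicate 2 minus replicate 1, the siScr arrays differed by a median of 0.20 on this list and the siErbB4 arrays by -0.40. In siErbB4 replicate 2, 21 of the 23 genes lay above the siScr mean. The list's median there was 0.13 over siScr replicate 2 and 0.26 over siScr replicate 1. The 0.19 is a distance from the siScr mean and the 0.20 a distance between single arrays, so they are unlike measures. Whether the rise in siErbB4 replicate 2 exceeded the spread between the siScr arrays was not tested.

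The cholesterol synthesis list fell in the siErbB4 arrays. All 25 listed genes were tested, 23 had a negative log2 difference, and at 13 of them the groups did not overlap. The adjusted p by camera was 3.12e-05 (Benjamini-Hochberg), and the adjusted p = 0.935 with an estimated correlation. No member was called over all genes, and 0 were called when adjusted over the list alone. The sterol dehydrogenase gene Nsdhl gave -0.51 (SE 0.16) and Dhcr7, which encodes the reductase of the last step to cholesterol, gave -0.53 (SE 0.17). Sqle at 0.03 (SE 0.13) and Stard4 at 0.13 (SE 0.17), named after their values were seen, were the members on the other side. The median was -0.08 without siScr replicate 1, where the call ended with an adjusted camera p of 0.164 (Benjamini-Hochberg; 3.03e-05 to 0.164 over the arrays left out in turn), and -0.17 without siErbB4 replicate 2.

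**Figure D2:**
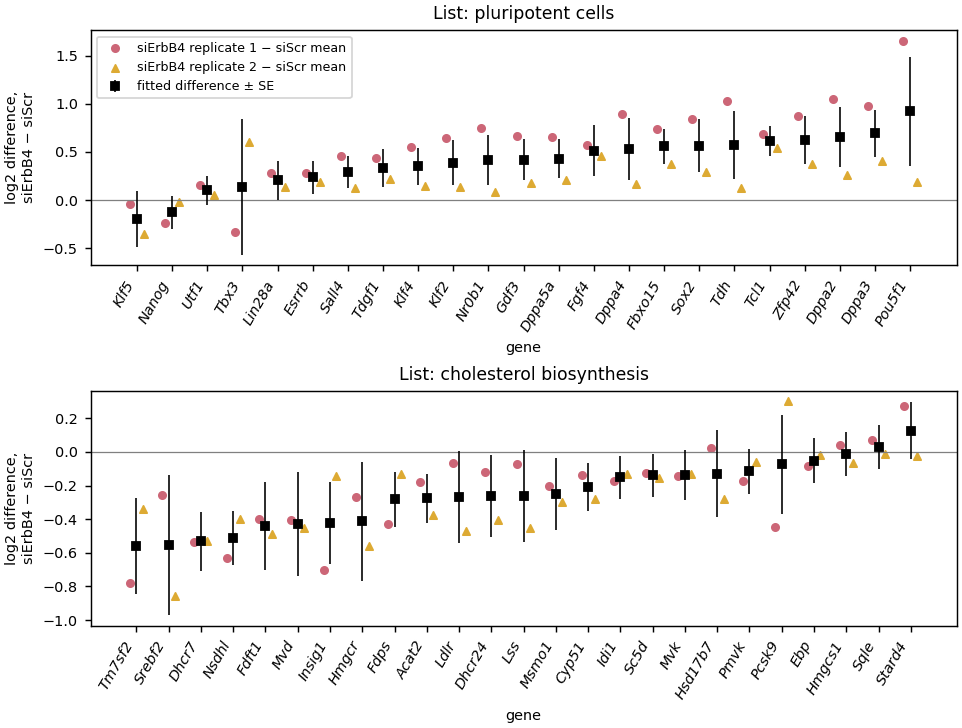
Log2 difference between siErbB4 and siScr (vertical axis) for each gene of the pluripotency list (upper panel) and of the cholesterol synthesis list (lower panel), with squares for the fitted difference, bars for its SE, and circles and triangles for siErbB4 replicates 1 and 2 against the siScr mean. Of the 23 pluripotency genes 21 lie above 0, and of the 25 cholesterol genes 23 lie below 0.

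Genes of the heart muscle cell itself showed no list that passed the camera test. The sarcomere list had a median log2 difference of -0.08 over 29 genes (adjusted camera p by Benjamini-Hochberg 0.514), with 21 genes negative and 8 positive. Its lowest p were those of Des, the muscle intermediate filament gene, at -0.44 (SE 0.17) and Ldb3 at 0.29 (SE 0.13). Named after their values were seen, the atrial and adult ventricular myosin heavy chain gene Myh6 gave -0.06 (SE 0.19, 95% interval -0.58 to 0.47) and the troponin gene Tnnt2 gave -0.06 (SE 0.15, 95% interval -0.47 to 0.36), and under quantile normalization Myh6 was 0.028 and Tnnt2 0.026. The cardiac transcription factors had a median of 0.10 over 31 genes (adjusted p 0.423), with Tbx20 at 0.25 (SE 0.16), Nr2f2 at 0.26 (SE 0.19) and, also named afterwards, Nkx2-5 at -0.14 (SE 0.33). Calcium handling genes had a median of -0.01 over 24 genes (adjusted p 0.876), with Fkbp1b at -0.21 (SE 0.14). Ion channels and connexins had a median of 0.09 over 20 genes (adjusted p 0.287), with the connexin gene Gja1 at 0.35 (SE 0.15) and Kcnd2 at 0.73 (SE 0.57; 0.02 to 1.45 with arrays left out), the latter well above background on 1 siScr array. Genes of hypertrophy and cardiac stress had a median of -0.08 over 19 genes (adjusted p 0.602), with Xirp2 at 0.34 (SE 0.20) and Gdf15 at -0.23 (SE 0.19).

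Markers of other cell types that such cultures can hold were compared in the same way. The fibroblast and extracellular matrix list had the median furthest from 0 of all 28 lists, -0.45 over 26 genes, with 23 negative, and an adjusted camera p by Benjamini-Hochberg of 0.0504. With the preset correlation it passed the threshold under 6 of the 9 alternative settings that left the replicate number out, quantile normalization among them (adjusted p 0.0391, in a range of 0.00975 to 0.0636 over the 9). In the fit itself it had an adjusted p = 0.935 with an estimated correlation. The 2 siScr arrays differed by a median of -1.14 on this list (replicate 2 minus replicate 1), and without siScr replicate 1 its median turned to 0.31. Col6a2 gave -0.72 (SE 0.31) and the collagen receptor gene Ddr2 -0.49 (SE 0.22). Smooth muscle genes had a median of -0.20 over 15 genes and endoderm and hepatic genes 0.20 over 22 genes, both with an adjusted p of 0.0708. Their genes with the lowest p were Des and the proteoglycan gene Cspg4 (-0.20, SE 0.16), and the keratin gene Krt18 (0.25, SE 0.13) and Foxa3 (0.53, SE 0.32). The endothelial list had a median of -0.07 over 17 genes, with Plvap at -0.55 (SE 0.26) and Mmrn2 at 0.36 (SE 0.23). Blood cell genes had a median of -0.15 over 10 genes, with Itgam at -0.19 (SE 0.15) and Fcer1g at -0.92 (SE 0.92), and epicardial genes -0.14 over 12 genes, with Aldh1a2 at -0.19 (SE 0.15) and Scx at -0.27 (SE 0.24). Neural genes had a median of -0.03 over 17 genes, with Gfap at 0.41 (SE 0.16). The endothelial, blood, epicardial and neural lists each had an adjusted p of 0.602.

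Cell cycle genes had a median of 0.17 over 37 genes (adjusted camera p by Benjamini-Hochberg 0.175), with the replication gene Mcm4 at 0.28 (SE 0.34) and Uhrf1 at 0.37 (SE 0.47). Genes fed by growth factor signalling, the MAPK feedback and immediate early list, had a median of -0.02 over 23 genes (adjusted p 0.602), with Fos at 0.40 (SE 0.13) and Egr2 at 0.93 (SE 0.31), the latter well above background on 1 siScr array. The interferon list had a median of 0.0072 over 25 genes (adjusted p 0.602). Its gene Cxcl10, given above, had the largest positive difference, and Ifit1, well above background on 1 siErbB4 array, gave -0.64 (SE 0.24). Inflammatory cytokines had a median of 0.0021 over 17 genes (adjusted p 0.602), with the NF-kappaB inhibitors Nfkbia at 0.34 (SE 0.18) and Tnfaip3 at 0.32 (SE 0.17). The p53 targets had a median of 0.07 over 23 genes (adjusted p 0.287), with Trp53inp1 at 0.38 (SE 0.19) and Bbc3 at 0.35 (SE 0.21). The unfolded protein and amino acid stress list had a median of -0.04 over 26 genes, with Sdf2l1 at -0.38 (SE 0.17) and Pdia4 at -0.51 (SE 0.31), and the heat shock list -0.0017 over 15 genes, with Hspb8 at -0.25 (SE 0.16) and Hsp90aa1 at 0.22 (SE 0.19). Both had an adjusted p of 0.602.

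Among metabolic genes, glycolysis had a median of -0.11 over 23 genes (adjusted camera p by Benjamini-Hochberg 0.978), with the glucose transporter genes Slc2a3 at 0.50 (SE 0.24) and Slc2a1 at 0.22 (SE 0.15). Oxidative phosphorylation had a median of -0.01 over 41 genes (adjusted p 0.728), with Uqcrc1 at -0.25 (SE 0.18) and Ndufa8 at 0.24 (SE 0.22). Fatty acid oxidation had a median of -0.01 over 26 genes (adjusted p 0.602), with the short-chain dehydrogenase gene Acads at -0.55 (SE 0.14) and Ucp3 at -0.53 (SE 0.19). The hypoxia list had a median of 0.13 over 21 genes (adjusted p 0.175), with Hmox1 at 0.52 (SE 0.28). Notch and Hippo targets had a median of 0.07 over 14 genes (adjusted p 0.514), with Lats2 at 0.17 (SE 0.14) and Hey1 at 0.19 (SE 0.18). Wnt and BMP targets had a median of -0.06 over 20 genes (adjusted p 0.602), with Notum at -0.30 (SE 0.13) and Id3 at -0.22 (SE 0.15), and the ERBB list -0.06 over its 8 genes (adjusted p 0.728).

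**Figure D3:**
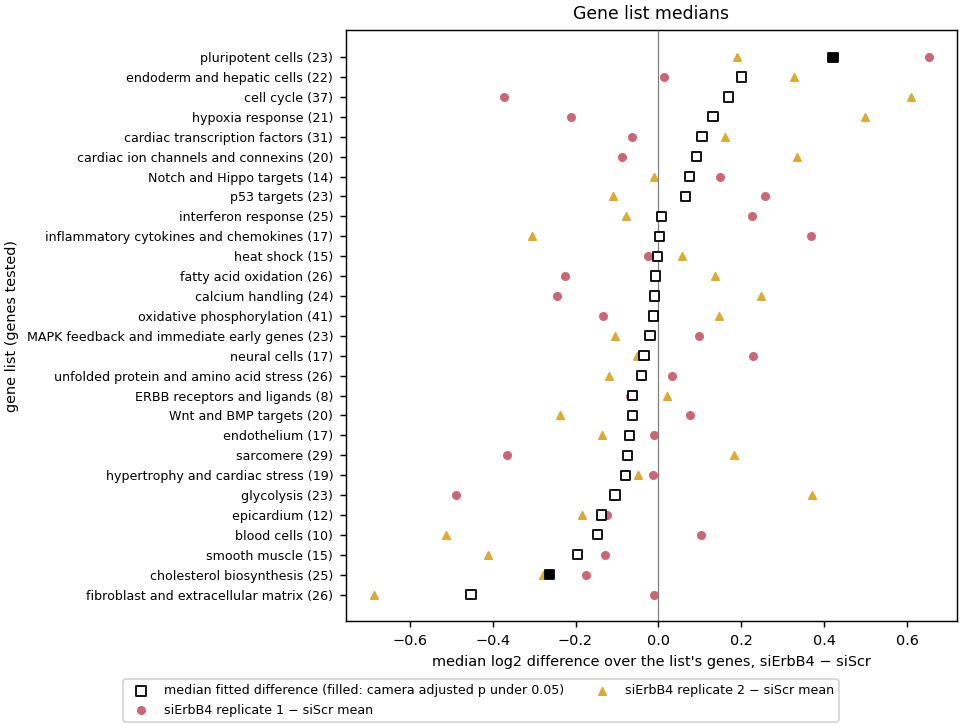
Median log2 difference between siErbB4 and siScr (horizontal axis) over the tested genes of each of the 28 lists (vertical axis), as squares for the fitted difference, filled where the camera test with the preset correlation passed, and as circles and triangles for siErbB4 replicates 1 and 2 against the siScr mean. The pluripotency list, at 0.42, and the cholesterol synthesis list, at -0.26, are the filled squares.

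Of the 28 lists, 2 were called by camera with the preset correlation, 0 with an estimated correlation and 0 by fry, whose lowest Benjamini-Hochberg adjusted p was 0.990. No list had a member called over all genes, and 0 lists had one adjusted over the list alone. The ERBB list had a negative median and test and a positive mean. The calcium, MAPK, heat shock, oxidative phosphorylation and neural lists had a negative median beside a positive mean and a positive camera direction, and the inflammatory list a negative mean beside a positive median and camera direction. Across genes, which are not independent replicates, the log2 values of siScr replicate 2 and siErbB4 replicate 2 correlated at 0.997 and those of siScr replicate 1 and siErbB4 replicate 1 at 0.994, above the 0.987 between the siScr arrays and the 0.990 between the siErbB4 arrays. On data simulated with the observed spread between arrays over the same 20726 features, 3.73% of 2-fold, 80.7% of 4-fold and 95% of 8-fold changes were called. The simulated arrays varied independently, while in the data the deviations of same-numbered arrays from their group means correlated at 0.679. These rates therefore need not hold for the data.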

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

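Of the tests in this part, only those of Nanog, Klf5, Pou5f1, Sqle, Stard4, Myh6, Tnnt2 and Nkx2-5 were chosen only after the result was seen. The count of called genes was 0, in each direction, under every alternative run, and the lowest adjusted limma p ranged from 0.0829 with the replicate block to 1.00 with normexp, with 185 to 1547 features at an unadjusted p under 0.05. The arrays grouped by replicate number: across genes, deviations of same-numbered arrays from their group means correlated at 0.679. Same-numbered arrays also correlated at 0.997 and 0.994, above the 0.987 and 0.990 within the groups. No label says what the numbers stand for, and there are only 2 pairs, so the main fit has no block. Its error therefore holds the difference that same-numbered arrays share, and 366 features had an unadjusted p under 0.05 there. With the replicate number as a block, 0 genes were called, 1547 had an unadjusted p under 0.05, and 6 lists were called in place of 2, the added lists being cell cycle, fibroblast, smooth muscle and endoderm, with an adjusted camera p of 1.40e-05 for fibroblast (Benjamini-Hochberg). Between same-numbered arrays the fibroblast median was -0.78 for replicate 1 and -0.15 for replicate 2, and the pluripotency median 0.67 and 0.13. No list was called with camera's estimated correlation (0) or by fry (0), and 4 were called with normexp and 4 with median scaling. Leaving out each array in turn gave 11 to 13 called lists. The pluripotency list was called under all 10 other alternatives, with medians of 0.40 to 0.45, and with every array left out (0.19 to 0.65). The cholesterol list was called under all 10 (-0.28 to -0.24), and with arrays left out ranged from -0.31 to -0.08, where its call ended without siScr replicate 1. A lone array is assumed there to vary like the other group. The cause of these changes was not tested. The slide block was not run, since there was 1 slide, and lists were not run on separate probes. Signal over background limits Erbb4, whose difference ranged from -1.89 to 0.53 with arrays left out.

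Under the alternatives that kept all 4 arrays, 12 list results passed that had not, 7 of them the fibroblast list, and these medians or differences reversed or fell to 0, none past the threshold and the cause not tested. With normexp, interferon was -0.0018, heat shock 0.0075, Nrg2 -0.035 and Egf -0.0061. With quantile normalization, sarcomere was 0, calcium handling 0.012, heat shock 0.041, oxidative phosphorylation 0.061, fatty acid oxidation 0.013, Myh6 0.028 and Tnnt2 0.026. With median scaling, calcium handling was 0.018, MAPK 0.0066, heat shock 0.025, oxidative phosphorylation 0.014 and fatty acid oxidation 0.019. With no filter, neural cells were 0.16. With the mean of a gene's probes, calcium handling was 0.010, heat shock 0.0036, Egfr -0.27 and Nanog 0.18. Reversals included, 24 of 80 named genes moved by over 1.5 times with normexp, 8 with the mean of probes, 6 with median scaling and 4 with quantile normalization. Beside reversals and the genes with the lowest p, normexp gave Kcnd2 0.25, Egr2 0.30, Ifit1 -0.15, Ddr2 -0.25, Plvap -0.27, Gfap 0.017, Foxa3 0.17, Aldh1a2 -0.054, Tgfa -0.084 and Nrg1 -0.025. The mean of probes gave Ldb3 0.077, Tbx20 0.14, Trp53inp1 0.24, Lats2 0.062, Stard4 0.032 and Myh6 -0.025. Leaving out arrays reversed 17 of 80 named genes and 26 of 28 lists at least once. It moved 53 of the 80 genes by over 1.5 times, and of the 36 that did not reverse the widest ranges were Pou5f1 0.19 to 1.65, Kcnd2 0.015 to 1.45, Pdia4 -0.91 to -0.11, Egr2 0.53 to 1.33, Col6a2 -1.11 to -0.32 and Hmox1 0.17 to 0.87.

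With arrays left out in turn, log2 differences ranged for these genes as Egf -0.12 to 0.13, Egfr -0.58 to 0.76, Epgn -0.55 to 0.26, Erbb2 -0.28 to 0.14 and Fcer1g -2.09 to 0.25. Other genes ranged as Hbegf -0.39 to 0.13, Klf5 -0.53 to 0.14, Mcm4 -0.11 to 0.66, Myh6 -0.24 to 0.13, Nkx2-5 -0.46 to 0.18 and Nrg1 -0.30 to 0.20. Further genes ranged as Nrg2 -0.31 to 1.37, Scx -0.56 to 0.014, Sqle -0.014 to 0.072, Stard4 -0.023 to 0.27, Tnnt2 -0.17 to 0.056 and Uhrf1 -0.20 to 0.95. List medians ranged for ERBB receptors and ligands -0.22 to 0.081, MAPK feedback and immediate early genes -0.10 to 0.12, Notch and Hippo targets -0.065 to 0.18, Wnt and BMP targets -0.34 to 0.088, blood cells -0.29 to 0.65 and calcium handling -0.27 to 0.25. Further medians ranged for cardiac ion channels and connexins -0.19 to 0.35, cardiac transcription factors -0.12 to 0.20, cell cycle -0.48 to 0.77, endoderm and hepatic cells -0.14 to 0.33, endothelium -0.24 to 0.042 and epicardium -0.30 to 0.19. More medians ranged for fatty acid oxidation -0.23 to 0.16, fibroblast and extracellular matrix -1.06 to 0.31, glycolysis -0.49 to 0.37, heat shock -0.024 to 0.068, hypertrophy and cardiac stress -0.11 to 0.010 and hypoxia response -0.21 to 0.50. They also ranged for inflammatory cytokines and chemokines -0.53 to 0.47, interferon response -0.12 to 0.24, neural cells -0.27 to 0.25, oxidative phosphorylation -0.19 to 0.19, p53 targets -0.11 to 0.31 and sarcomere -0.37 to 0.18. The last ranged for smooth muscle -0.77 to 0.16 and unfolded protein and amino acid stress -0.18 to 0.057.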

Other observations

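The split by replicate number, the lists of second markers and the tests on them were chosen only after the arrays had been seen to group by replicate number. The test of the cardiomyocyte share was also written after its result was seen. The genes named here were chosen after their values were seen.

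Over both transfection groups together, the sarcomere, calcium handling and cell cycle lists were higher in the replicate 2 arrays, and the inflammatory list was higher in the replicate 1 arrays, by camera with the preset correlation and by fry. With an estimated correlation these calls were lost (adjusted p = 0.306 for each). In simulations of the group comparison, camera with an estimated correlation called 0 of 20 lists shifted by 0.4, so such a loss does not show an unchanged list. The fibroblast and matrix list was higher in the replicate 1 arrays by camera with the preset correlation alone (adjusted p = 0.345 with an estimated correlation and 0.105 by fry). With limma and the Benjamini-Hochberg method, 1085 of 20726 features were called between the numbers, 600 higher and 485 lower in replicate 2, against 0 between siErbB4 and siScr and 0 in the crossed split, with 4770, 366 and 152 at an unadjusted p under 0.05. Higher in replicate 2, as log2 differences, were the mitochondrial gene Mgarp (3.60), the lysozyme genes Lyz1 (3.42) and Lyz2 (3.24), near-identical copies that a probe may not separate, the connexin gene Gja5 (2.51), the myosin heavy chain antisense gene Mhrt (2.41), the ventricular transcription factor gene Irx4 (2.22) and the calcium channel gene Cacna1g (2.20). Lower in replicate 2 were Serpinb1a (-4.08), the macrophage receptor gene Marco (-3.63), the BMP antagonist gene Grem1 (-3.24), the matrix gene Tnc (-2.98) and the chemokine gene Ccl7 (-2.96). Of the cell cycle list 25 of 37 tested genes were called higher, with a median difference of 1.18 between the siScr arrays and 1.06 between the siErbB4 arrays, and of the calcium list 8 of 24 (0.56) and of the sarcomere list 6 of 29 (0.48). Of the fibroblast list 6 of 26 were called lower (median -0.98), among them Col1a1 (-2.27), Tgfbi (-2.50) and Postn (-1.89), and of the inflammatory list 6 of 17 (-0.58), with 1 more called higher. Camera with the preset correlation called 22 of 28 lists, camera with an estimated correlation 0 (lowest adjusted p 0.306, Benjamini-Hochberg), and fry 12, 6 in each direction. With the transfection group as a block 1518 features were called, 1034 of them shared, and all 15 genes compared kept their call, while quantile normalization ended that of Mgarp alone.

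An array-wide scaling difference predicts that quantile normalization ends most of these calls, and it left 962, of which 955 were shared, which argues against it as the whole cause. A difference in hybridisation or scanning between slide positions predicts shifted spike-in probes, and the median absolute log2 difference of 7 such probes was 0.0762, against 1.14 for the called genes. A lower share of cardiomyocytes in the replicate 1 cultures as the only cause would raise the markers of all other cells alike, but the endoderm and fibroblast medians lay 1.49 apart (95% bootstrap interval 0.879 to 1.97). The bootstrap resampled the genes of each list as if independent, so its interval does not measure the spread between cultures. A candidate explanation is more fibroblast-like cells in the replicate 1 cultures. A second fibroblast list that shares no gene with any of the 28 lists had a median of -0.966, with 23 of 26 genes lower in replicate 2 and 5 called. Among its genes with the highest signal, Lgals1 gave -1.85 and Fstl1 -0.18. The genes on the other side were Prrx2 at 0.55, Prrx1 at 0.06 and Pcolce at 0.03. Both fibroblast lists would also move together if the same cells changed their expression of such genes. The second list therefore cannot tell a larger share of these cells from such a change. It also does not bear on the cell cycle list, of which 25 of 37 genes were called higher in replicate 2. Whether this candidate accounts for those genes was not tested. Differences in culture or in the incubation of 6 or 24 hours, which the labels do not assign, stay open and untested, and both replicate 1 arrays lay side by side on the slide, as did both replicate 2 arrays.

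The higher pluripotency list in the siErbB4 arrays was set against an array-wide intensity trend, and its mean log2 difference of 0.40 lay at percentile 100 of 10000 random lists matched on signal, whose highest mean was 0.19. The random lists were drawn gene by gene, while the estimated correlation within the pluripotency list was 0.485. The percentile therefore bears only on a trend with signal and does not measure chance for genes that vary together. A candidate explanation is more undifferentiated cells in the siErbB4 replicate 1 culture, and a second pluripotency list that shares no gene with the 28 lists had a median of 0.50 there against the siScr mean, with 26 of 30 genes positive. Of its 5 genes with the highest probe signal, Chchd10 lay at -0.11 there against the siScr mean, Upp1 at -0.05, Slc7a3 at 0.26, Mybl2 at 0.37 and L1td1 at 1.12. The second list had a median of 0.27 in siErbB4 replicate 2, with 23 of 30 positive, and this was not tested against the spread between the siScr arrays. An effect of the knockdown stays open and untested, because the 1 probe named as Erbb4 was too dim to measure it and 2 arrays a group may differ by culture.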
